A study of Mus musculus with 34 samples.

How the data were processed

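RNA of the mouse cornea was measured on Affymetrix gene arrays. Per the labels, the mice were wild-type CB6, corneas were dissected from the globe, the epithelium of P28 was lifted off with dispase, and the stroma of P7 was taken by laser capture from sections of whole globes. The series' design text speaks of 1 time point for the layers, while the sample labels give P28 and P7, and the sample labels were followed. The labels do not say whether arrays of one age came from separate animals. Replicates 3 and 2 of 2 months carry the identifiers 1A and 1B, whose meaning the labels do not give.

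The values were used as deposited: 1 intensity per probe set and array, on a linear scale, which the authors made with Affymetrix Expression Console 1.1 and PLIER per the submitters' processing notes. The table held 35557 probe sets on 34 arrays and 2 missing values. On the 32 whole-cornea arrays the lowest intensity lay near 0 and the median between 188.2 and 240.6. On the 2 layer arrays the lowest intensity was 41.8 and 42.6 and the median 318 and 322, a higher floor than that of the whole-cornea arrays. The layer arrays were kept out of every fit by design. The number of arrays, 2 or 3 per age, limits the precision.

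Gene symbols came from the table of probe sets and genes given with the series matrix: 21789 probe sets had 1 symbol, 1621 had several and 12147 had none there. Only probe sets with 1 symbol were analysed as genes, 19938 distinct symbols in all. A probe set was kept if it lay above its array's median, taken over the probe sets with 1 symbol (the design had named all probe sets other than controls, which the annotation does not mark), on at least 2 of the 32 whole-cornea arrays. This kept 14329 probe sets. For a gene with several kept probe sets the one with the highest mean was used, which left 12998 genes. Intensities were put on a log2 scale after adding 16, with no further normalization between arrays.

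The design, the comparisons, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. A linear model with 1 mean per age for the 12 ages was fitted to the 32 whole-cornea arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 20 residual and 4.1 prior degrees of freedom), so all ages share 1 estimate of the spread. The comparisons were E17.5 against E14.5, P7 against E17.5, P28 against P7, 2 months against E14.5, the mean of 1 year, 18 months and 2 years against the mean of 2 and 6 months, and each age against the one before it. All tests were two-sided, with Benjamini-Hochberg adjustment over the 12998 genes within a comparison. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1, and for the moderated F-test over the 12 ages with a largest minus smallest age mean of at least 1. Printed intensities of an age are means with SD over its arrays, and differences are on the log2 scale with the SE of the fit.

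The 29 gene lists hold 459 entries, of which 420 had a probe set. They cover layers of the cornea, matrix, cell cycle, metabolism, immune and clock genes, and tissues beside the cornea. For each list the called members were counted over all genes tested and again when adjusted over the list alone. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists within a comparison, and again with an estimated correlation between genes. At the preset correlation 61 of 135 list results passed. With an estimated correlation the calls that held were those of blood genes before birth, corneal epithelial products after birth, clock genes, corneal epithelial products, epithelial transcription factors and blood genes at 2 months against E14.5, and peripheral nerve genes with ageing.

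The named genes are, per comparison, any of the 12 called genes with the largest rise and the 12 with the largest fall whose arrays do not overlap between the sides, and any list member. Symbols of unnamed transcripts were left out, among which symbols beginning with AA were counted as expressed sequences. Steps name the 3 genes with the largest rise and fall, the F-test the 10 genes with the highest F, and the layers the 12 genes with the largest difference in each direction.

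The layers have 1 array each, so no test was made: genes above the array median on either array were counted at a 4-fold difference, list medians were set against 10000 random lists matched on mean expression, and an interval for a share (exact binomial) covers counting error only.

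Alternatives tried were other filters, offsets, normalizations and ways to join probe sets, trend and robust moderation, array weights, other thresholds, the replicate number as a block, the 1A and 1B arrays averaged, the compared groups alone, each array left out in turn, and other ages for the ageing and layer comparisons. An array was called rich in another tissue when the median of that tissue's list lay at least 2 log2 units above its 32-array median, and the comparisons were repeated without such arrays, a choice made after seeing the data. A change of sign was counted as a reversal only where the value was called in either setting. The fit was tested on simulated data with 12998 genes: 88.1% to 100% of genes given a log2 shift of 1.5, 2 or 3 were called, with 0 to 5 false calls per comparison. Camera called the 1 shifted set and 0 of 27 others. The simulated genes were independent of each other, so this could not show false list calls that come from correlation between genes. The simulated arrays also held no array batch, no other tissue and no difference in sex. False calls of genes that such differences could bring were therefore not measured. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The 12147 probe sets without a gene and the 1621 with several were left out of the gene tests because their signal has no single gene.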

Results

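Gene expression in the cornea of wild-type CB6 mice was measured with expression arrays at 12 ages from E14.5 (embryonic day 14.5) to 2 years. Each of E14.5, E15.5, E17.5, P3 (postnatal day 3), P7, P14, P28 and 2 months was represented by 3 whole-cornea arrays, and each of 6 months, 1 year, 18 months and 2 years by 2. With 1 array of epithelium from P28 and 1 array of stroma from P7, the series held 34 arrays, of which 32 were of whole cornea. The median intensity of the probe sets lay between 188.2 and 240.6 on the whole-cornea arrays, and was 318 and 322 on the layer arrays. Across genes, the log2 values of the 28 pairs of arrays of one age correlated with r between 0.879 and 0.985. The labels do not say whether arrays of one age came from separate animals, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

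Genes of tissues that lie next to the cornea were measured on some of the arrays. The median of 17 lens genes lay at least 2 log2 units above its 32-array median on 6 arrays: E14.5 replicates 2 and 3, P14 replicate 2, P28 replicate 2, 2 months replicate 1 and 6 months replicate 2. The median of 10 skeletal muscle genes did so on E17.5 replicates 1 and 3, and that of 11 retina genes on 6 months replicate 1. The embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 had mean intensities of 12420 ± 2730, 10420 ± 2580 and 5837 ± 2390 (SD, n = 3) at E14.5, against 159.7, 199.7 and 52.1 at E15.5. A group of 8 unnamed probe sets read 1501 or more on the 18 arrays of E14.5 to P14 and 12.8 or less on the 14 arrays of P28 to 2 years. By these probe sets, whose targets the annotation used here does not name, the whole-cornea arrays fell into 2 sets that divide the ages between P14 and P28, called array batches here.

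Between E14.5 and 2 years, 5279 of 12998 genes tested changed (40.6%). The genes with the highest F statistic included Aldh3a1, an aldehyde dehydrogenase abundant in corneal epithelium, Krt12, the keratin of corneal epithelium, Col11a1, a fibrillar collagen chain, and Hlf, a clock-controlled transcription factor. The mean intensity of Aldh3a1 was 31 ± 7.14 at E14.5, 476 ± 153 at E15.5, 5514 ± 1010 at P7 and 10210 ± 496 at 2 months (SD, n = 3 each). Krt12 had 55.5 ± 7.32 at E14.5, 7494 ± 1880 at E15.5, 2120 ± 330.0 at P3 and 12950 ± 288 at 2 months. Col11a1 had 377 ± 175 at E14.5, 2222 ± 621 at P7, 393 ± 50 at P28 and 146 ± 61.9 at 2 months, and its mean at 18 months was 5.47 ± 2.56 (n = 2). Within the 6 ages of the earlier array batch 2407 genes changed, and within the 6 ages of the later batch 892.

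**Figure D1:**
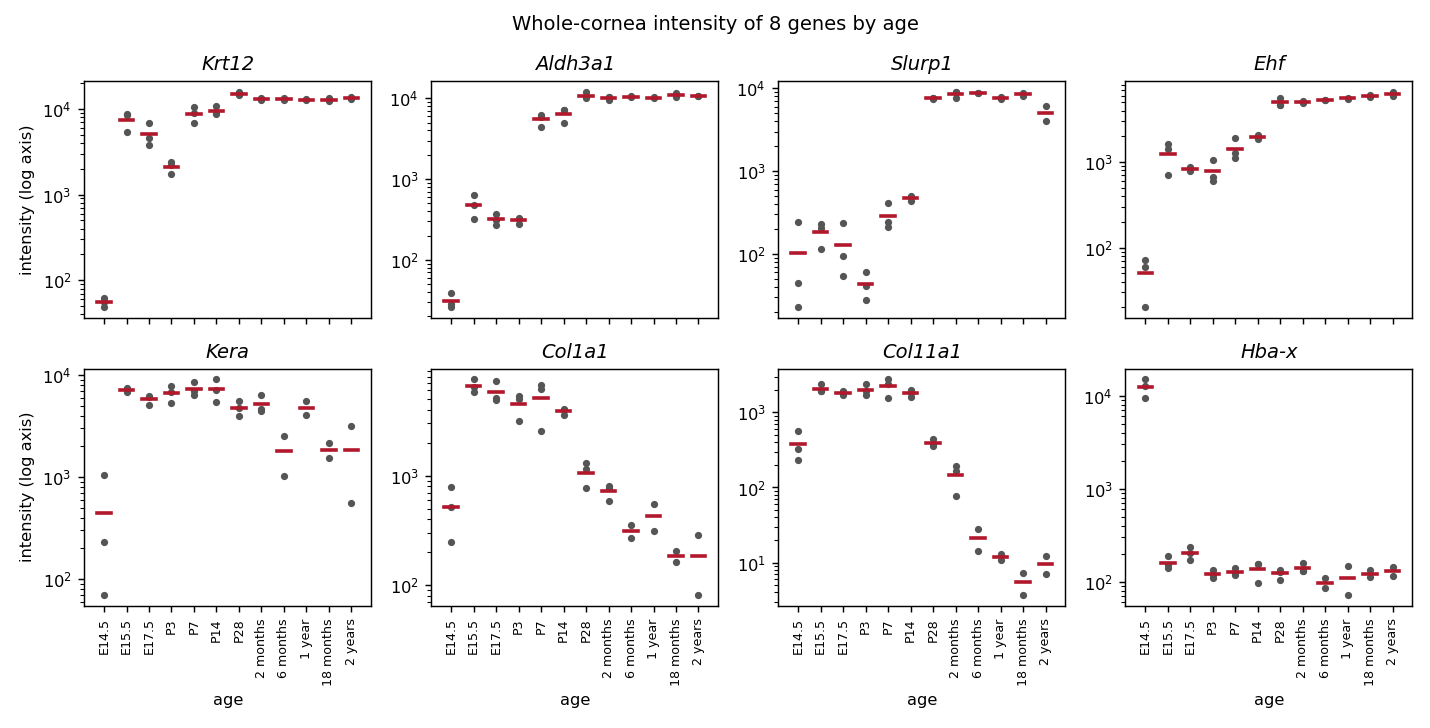
Intensity of 8 genes on each whole-cornea array (points, log axis) against age, with the mean of each age as a red line. Krt12 rose from 55.5 to 7494 between E14.5 and E15.5, Slurp1 stood at 476 at P14 and 7629 at P28, and Col11a1 had a mean of 5.47 at 18 months.

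Changes between neighbouring ages were concentrated in a few steps. From E14.5 to E15.5, 1357 genes changed, 954 of them upward, and from P14 to P28, 994 genes changed, 539 of them upward. The other steps called 74 genes from E15.5 to E17.5, 246 from E17.5 to P3, 257 from P3 to P7, 274 from P28 to 2 months, 163 from 2 to 6 months, 27 from 6 months to 1 year, 111 from 1 year to 18 months and 58 from 18 months to 2 years. By limma no gene was called from P7 to P14, where 819 genes had an unadjusted p under 0.05. With no filter, 1.77% of 1015 olfactory receptor genes were called from E17.5 to P3, against 1.42% of all genes. From 2 to 6 months it was 0.89% against 0.91%, and from 1 year to 18 months 0.79% against 0.68%. At these steps the share called was thus close to that of this family. It was 0.79% against 7.09% from E14.5 to E15.5 and 0% against 5.05% from P14 to P28. At the other steps the family's share was lower, or both were 0. The step from E14.5 to E15.5 was led upward by Krt12, with a log2 difference of 6.68, and by A2m, a protease inhibitor, with 5.86, while Crygd, a lens crystallin, and Hbb-bh1 gave -6.41 and -6.35. In the same step 10 of 14 fibrillar and associated collagens rose, with a list median of 3.10, and 25 of 27 cell cycle genes fell, with a median of -1.72. Gkn1, a gastrokine, rose by 4.24 from P14 to P28, a step at which age and array batch cannot be told apart.

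**Figure D2:**
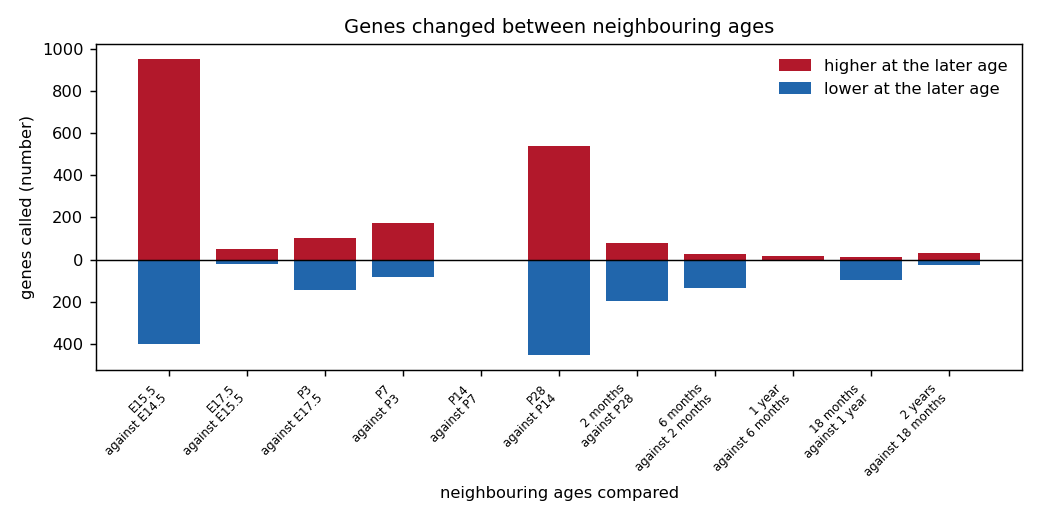
Number of genes called between neighbouring ages, with genes higher at the later age above 0 (red) and genes lower at the later age below 0 (blue). The steps from E14.5 to E15.5 (1357 genes) and from P14 to P28 (994 genes) are the tallest, and the step from P7 to P14 has 0 genes.

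The prenatal comparison set E17.5 against E14.5. Members of the epithelial, collagen and matrix lists rose and members of the lens, blood and cell cycle lists fell. Of these list results only that of the blood genes held with an estimated correlation between genes. Krt12 rose by 6.11 log2 units (SE 0.19, adjusted p = 2.4e-17), Krt13, a keratin of mucosal epithelia, by 5.10, and Krt6a by 4.19. Kera, the keratocyte proteoglycan keratocan, rose by 4.36 (SE 0.57, adjusted p = 5.3e-06), from 448 ± 520.0 to 5809 ± 640.0 (SD, n = 3 each). Col6a1, Thbs4 and Thbs2, genes of matrix proteins, rose by 4.22, 5.23 and 4.32. Hba-x fell by 5.82 (SE 0.20, adjusted p = 2.0e-16). In all, 943 of 12998 genes changed, 762 upward and 181 downward.

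By group, 9 of 17 corneal epithelial products rose before birth (9 when adjusted over the list alone), among them Upk1b by 3.32, Mal by 3.95 and Aldh3a1 by 2.83, while Aldh1a1 fell by 2.02 (adjusted p = 5.0e-10 by camera, and adjusted p = 0.0631 with an estimated correlation). Of the epithelial transcription factors 5 of 15 rose (5 when adjusted over the list alone), including Ehf by 3.78, Klf5 by 1.85 and Klf4 by 1.78 (adjusted p = 1.8e-04 by camera, and adjusted p = 0.161 with an estimated correlation). Pax6, the eye regulator, gave 0.38 (adjusted p = 0.248). Among genes of junctions and barrier 11 of 22 rose (11 when adjusted over the list alone), with the desmosomal genes Dsc3 at 2.83, Dsg3 at 2.73 and Ppl at 2.74 (adjusted p = 1.5e-07 by camera, and adjusted p = 0.163 with an estimated correlation). For the fibrillar and associated collagens 10 of 14 rose (10 when adjusted over the list alone), with Col6a3 at 3.92, Col14a1 at 3.60 and Col1a1 at 3.56 (adjusted p = 8.0e-11 by camera, and adjusted p = 0.0804 with an estimated correlation). Of the small leucine-rich proteoglycans 8 of 11 rose and 1 fell (8 higher and 1 lower when adjusted over the list alone; adjusted p = 7.1e-05 by camera, and adjusted p = 0.151 with an estimated correlation). Among genes of collagen processing and other matrix, 13 of 19 rose (13 when adjusted over the list alone), with Pcolce at 2.82 and Plod1 at 2.49 (adjusted p = 3.2e-08 by camera, and adjusted p = 0.135 with an estimated correlation). Cell cycle genes went the other way: 11 of 27 fell (11 when adjusted over the list alone), with the mitotic checkpoint gene Bub1 at -1.82 (adjusted p = 2.3e-13 by camera, and adjusted p = 0.121 with an estimated correlation).

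Of the lens genes 12 of 17 fell (12 when adjusted over the list alone), with Crygd at -6.41 (SE 1.60), and the lens list was high on 2 of the 3 E14.5 arrays (adjusted p = 9.0e-06 by camera, and adjusted p = 0.353 with an estimated correlation). Of the blood genes 3 of 5 fell (3 when adjusted over the list alone; adjusted p = 3.2e-08 by camera, and adjusted p = 0.037 with an estimated correlation). Skeletal muscle genes rose in 6 of 10 cases (6 when adjusted over the list alone), with Acta1 at 2.57, and the muscle list was high on 2 of the 3 E17.5 arrays (adjusted p = 3.4e-04 by camera, and adjusted p = 0.306 with an estimated correlation). Without the lens-rich arrays only replicate 1 of E14.5 was left, and Bub1 was no longer called while Pax6 newly was. Without the muscle-rich arrays only replicate 2 of E17.5 was left, and Acta1 and Crygd were no longer called. That array correlated with the other E17.5 arrays at r = 0.907 and 0.902, against 0.973 between those. Counts of called genes are not given for these fits, since an age is left with 1 array. With E15.5 in place of E14.5 the comparison called 74 genes, 51 upward and 23 downward. Xist read 573 to 4471 on the E14.5 arrays and 24.9 to 283 on the E17.5 arrays.

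The perinatal comparison set P7 against E17.5. Members of the epithelial product, mucin and clock lists rose, and members of the muscle, pigment cell and vessel lists fell. Of these list results only that of the epithelial products held with an estimated correlation. Aldh3a1 rose by 4.04 log2 units (SE 0.18, adjusted p = 2.7e-13), and the transmembrane serine protease genes Tmprss11d, Tmprss11g and Tmprss11a rose by 4.19, 3.46 and 3.43. Krt6b rose by 3.94, from 166 ± 37.6 to 2782 ± 657 (SD, n = 3 each), and Aqp5, a water channel, by 3.25 (SE 0.30, adjusted p = 8.5e-08). Nrk, a kinase gene, and Tmem255a gave -5.56 and -4.25. In all, 647 genes changed, 366 upward and 281 downward.

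Of the corneal epithelial products 8 of 17 rose after birth (10 when adjusted over the list alone), among them Gsto1 by 2.64, Tkt, the transketolase gene, by 1.83 and Krt14 by 1.58 (adjusted p = 6.2e-14 by camera, and adjusted p = 0.027 with an estimated correlation). Mucins and mucosal surface genes rose in 5 of 10 cases (5 when adjusted over the list alone), with the galectin gene Lgals3 at 2.40, Muc4 at 2.27 and Muc20 at 2.05 (adjusted p = 1.5e-04 by camera, and adjusted p = 0.0578 with an estimated correlation). Of the circadian clock genes 5 of 15 rose (5 when adjusted over the list alone), including Nr1d1 by 2.08 and Per3 by 1.83 (adjusted p = 7.8e-06 by camera, and adjusted p = 0.0578 with an estimated correlation). Antigen processing genes rose in 2 of 10 cases (2 when adjusted over the list alone), with the immunoproteasome genes Psmb9 at 2.07 and Psmb8 at 1.98 (adjusted p = 7.5e-04 by camera, and adjusted p = 0.0578 with an estimated correlation). Interferon response genes rose in 2 of 13 (2 when adjusted over the list alone), with Ifih1, a sensor of viral RNA, at 1.61 (adjusted p = 0.0158 by camera, and adjusted p = 0.401 with an estimated correlation). Among the corneal endothelial genes 1 of 9 rose (2 when adjusted over the list alone): Slc4a11, an endothelial transporter, by 2.78, with a list result of adjusted p = 0.188 by camera, and adjusted p = 0.479 with an estimated correlation. None of the 14 collagens was called by limma, and Col1a1 gave -0.27 and Col14a1 -0.59 (1 at an unadjusted p under 0.05).

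Downward, 8 of 10 skeletal muscle genes fell (8 when adjusted over the list alone), with Mylpf at -4.41 and Acta1 at -3.18 (adjusted p = 1.2e-09 by camera, and adjusted p = 0.058 with an estimated correlation). Pigment cell genes fell in 5 of 8 cases (5 when adjusted over the list alone), with Dct, an enzyme of melanin synthesis, at -3.94 (adjusted p = 1.8e-07 by camera, and adjusted p = 0.058 with an estimated correlation). Of the vessel genes 5 of 9 fell (5 when adjusted over the list alone), with Emcn at -2.80 (adjusted p = 1.7e-05 by camera, and adjusted p = 0.0578 with an estimated correlation). Slc2a1, a glucose transporter, gave -1.70, and the matrix genes Vcan and Fbn2 -2.75 and -1.58. Without the 2 muscle-rich E17.5 arrays only replicate 2 of E17.5 was left, so no count of called genes is given. In that fit the calls of Mylpf, Nrk, Emcn, Krt14 and Lgals3 were lost. With weights estimated per array the split was 330 upward and 363 downward. Sex differed in part: Xist read 24.9 to 283 on the E17.5 arrays and 5353, 66.1 and 4693 on the P7 arrays, and none of 4 sex-linked genes was called by limma (1 higher and 3 lower when adjusted over the list alone, and 4 at an unadjusted p under 0.05).

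The comparison of P28 with P7 spans eyelid opening. Members of the epithelial transcription factor, junction and interferon lists rose, and members of the collagen and matrix lists fell. None of these list results held with an estimated correlation. Slurp1, a secreted epithelial protein, rose by 4.70 log2 units (SE 0.46, adjusted p = 6.0e-08), from 289.8 ± 106 to 7629 ± 133 (SD, n = 3 each). Psca rose by 4.22, Gkn1 by 4.33, Ly6g6c by 4.53 and Cyp2f2, a cytochrome P450 gene, by 3.98. Col14a1 fell by 4.53 (SE 0.42, adjusted p = 2.8e-08), from 6836 ± 1160 to 307 ± 179, and Otor, Tac1, the substance P precursor, and Mdk, the growth factor midkine, lay at -5.18, -4.15 and -3.34. In all, 1365 genes changed, 773 upward and 592 downward.

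For the fibrillar and associated collagens 10 of 14 fell between P7 and P28 (10 when adjusted over the list alone), with Col3a1 at -2.49, Col1a2 at -2.39 and Col1a1 at -2.16 (adjusted p = 5.9e-10 by camera, and adjusted p = 0.208 with an estimated correlation). Collagen processing and other matrix genes fell in 13 of 19 cases (13 when adjusted over the list alone), among them Fbn2 at -3.44, Postn, periostin, at -2.91 and Lox, lysyl oxidase, at -2.78 (adjusted p = 2.4e-11 by camera, and adjusted p = 0.208 with an estimated correlation). Of the small leucine-rich proteoglycans 5 of 11 fell (5 when adjusted over the list alone), with Aspn at -2.24 and Ogn at -2.35, while Kera gave -0.62 (adjusted p = 0.438) and the list adjusted p = 0.00635 by camera, and adjusted p = 0.394 with an estimated correlation. Corneal endothelial genes fell in 5 of 9 cases (5 when adjusted over the list alone), with Cdh2 at -2.75 and Slc4a4, a bicarbonate transporter, at -1.59 (adjusted p = 0.00837 by camera, and adjusted p = 0.342 with an estimated correlation). Periocular mesenchyme regulators fell in 4 of 12 (4 when adjusted over the list alone), including Twist2 and Prrx1 at -2.18 and -2.17 (adjusted p = 0.0134 by camera, and adjusted p = 0.394 with an estimated correlation).

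Upward, 9 of 15 epithelial transcription factors rose (9 when adjusted over the list alone), with Klf4 at 1.83 and Ehf at 1.82 (adjusted p = 1.4e-04 by camera, and adjusted p = 0.342 with an estimated correlation). Junction and barrier genes rose in 11 of 22 cases (12 when adjusted over the list alone), with Cldn7 at 1.77 and Dsc3 at 1.57 (adjusted p = 7.0e-04 by camera, and adjusted p = 0.508 with an estimated correlation). Interferon response genes rose in 5 of 13 cases (5 when adjusted over the list alone), with Ifih1 at 1.89 and Oasl2 at 1.70 (adjusted p = 0.0234 by camera, and adjusted p = 0.579 with an estimated correlation). Il1a, an epithelial cytokine, rose by 3.12, and the membrane mucin Muc15 by 3.33. Age and array batch cannot be told apart here, since P7 lies in the earlier batch and P28 in the later one, and within the earlier batch P14 against P7 gave 0 genes by limma. After a further quantile normalization 481 genes rose and 621 fell, and the share of rising genes went from 56.6% to 43.6%.

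**Figure D3:**
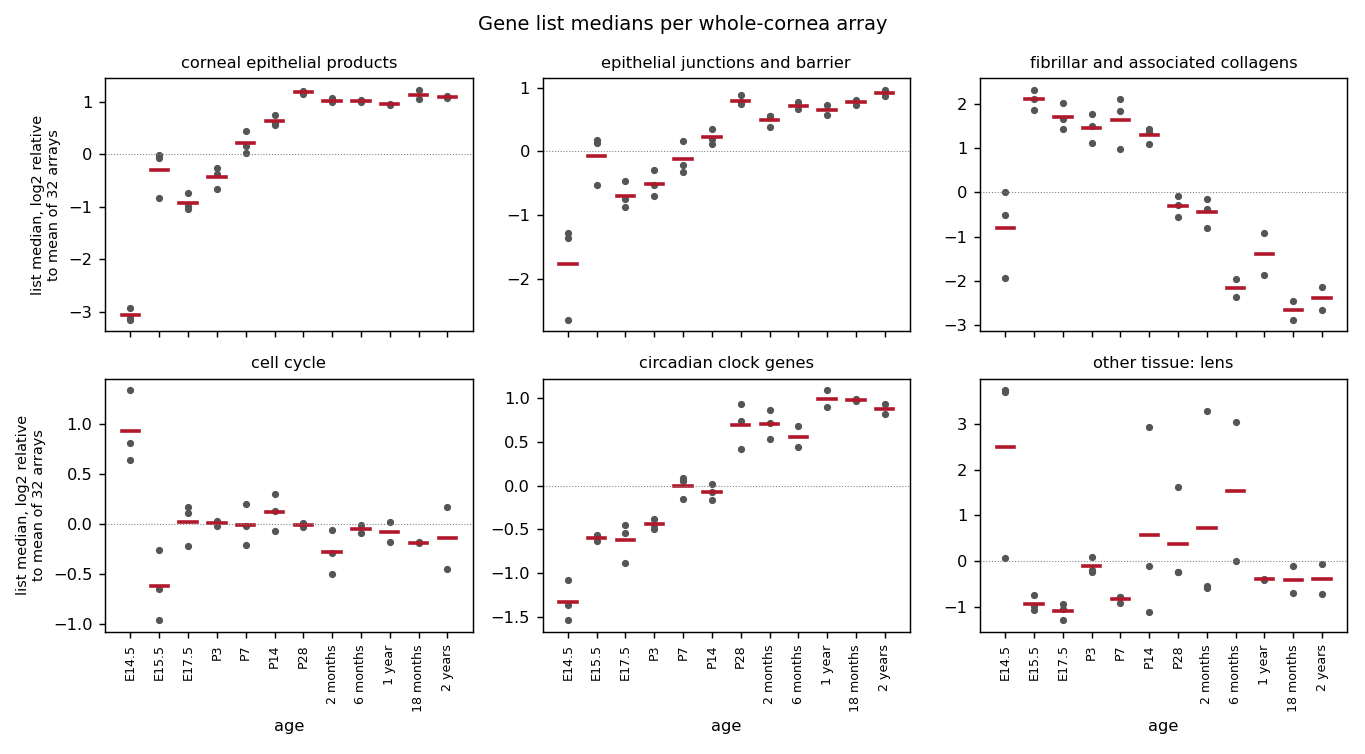
Median of 6 gene lists on each whole-cornea array (points), in log2 units relative to each gene's mean over the 32 arrays, with the mean of each age as a red line. The collagen list lies highest from E15.5 to P14, the epithelial products lie lowest at E14.5 and highest from P28 on, and the lens list is high on 6 single arrays of 5 ages.

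The comparison of 2 months with E14.5 gave the change from embryo to adult. Members of the epithelial product, transcription factor, junction and clock lists rose, and members of the cell cycle and blood lists fell. With an estimated correlation the results of the junction and cell cycle lists were lost and the other 4 held. Krt6b rose by 7.96 log2 units (SE 0.23, adjusted p = 2.4e-18), Aldh3a1 by 7.78, Krt12 by 7.51 and Adh7, an alcohol dehydrogenase, by 6.90. Krt6b, Aldh3a1 and Krt12 read below the array medians at E14.5, so the size of their rises depends on the offset added before log2. The same holds for the other rises from E14.5 given for these genes. Fabp6, Csta1 and Slurp1 rose by 7.38, 6.72 and 6.65. Vcan, the proteoglycan versican, fell by 4.92 (SE 0.42, adjusted p = 7.6e-10), and Gjc1, a connexin gene, Sox11 and Sfrp2 gave -4.61, -4.60 and -4.44. In all, 2117 genes changed, 1335 upward and 782 downward.

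Of the corneal epithelial products 14 of 17 were higher at 2 months (14 when adjusted over the list alone), with Psca at 6.42, Calml3 at 5.57 and Aqp5 at 5.23 (adjusted p = 2.0e-14 by camera, and adjusted p = 0.0194 with an estimated correlation). Epithelial transcription factors rose in 12 of 15 cases (12 when adjusted over the list alone), with Ehf at 6.35, Hopx at 4.30, Klf4 at 4.25 and Pax6 at 1.53 (adjusted p = 1.3e-08 by camera, and adjusted p = 0.0473 with an estimated correlation). Junction and barrier genes rose in 19 of 22 cases (19 when adjusted over the list alone), with Dsc3 at 5.13 and Ppl at 4.47 (adjusted p = 1.0e-10 by camera, and adjusted p = 0.146 with an estimated correlation). Of the circadian clock genes 10 of 15 rose (10 when adjusted over the list alone), with Hlf at 4.90, Nr1d1 at 3.86 and Dbp at 3.21, while Arntl gave -0.18 (adjusted p = 0.596) and the list adjusted p = 4.2e-09 by camera, and adjusted p = 0.0194 with an estimated correlation. The fit held no term for the time of day at collection. For clock genes a difference in it between ages could not be told apart from age, here and in the other comparisons. Antigen processing genes rose in 4 of 10 cases (4 when adjusted over the list alone), with Psmb8 at 3.61 and Psmb9 at 3.59 (adjusted p = 0.0495 by camera, and adjusted p = 0.307 with an estimated correlation). The fibrillar collagens went both ways, with Col6a1 at 2.67 and Col3a1 at -2.41, 3 of 14 higher and 3 lower (3 higher and 3 lower when adjusted over the list alone; adjusted p = 0.852 by camera, and adjusted p = 0.933 with an estimated correlation). Cell cycle genes fell in 18 of 27 cases (18 when adjusted over the list alone), with Bub1 at -2.44 and Kif11 at -1.86 (adjusted p = 1.0e-10 by camera, and adjusted p = 0.236 with an estimated correlation). Blood genes fell in 4 of 5 cases (4 when adjusted over the list alone; adjusted p = 6.2e-07 by camera, and adjusted p = 0.0279 with an estimated correlation), and retina genes rose in 6 of 11 (6 when adjusted over the list alone), with Gnat1 at 4.78 (adjusted p = 0.0495 by camera, and adjusted p = 0.573 with an estimated correlation). E14.5 and 2 months lie in different array batches, so age and batch cannot be told apart here; within the earlier batch, P14 against E14.5 called 1479 genes, 1129 upward and 350 downward. With E15.5 in place of E14.5, 1615 genes were called, 764 upward and 851 downward. The sex-linked genes differed as well: Xist read 5230 to 5676 on the 2-month arrays against 573 to 4471 at E14.5, and 3 of 4 sex-linked genes were called lower at 2 months. Kdm5d, a Y-linked gene, read 416, 1167 and 166 on the E14.5 arrays, against 5.12 to 22.3 at 2 months. The E14.5 arrays thus read both Xist and a Y-linked gene and cannot be assigned to 1 sex.

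The ageing comparison set the mean of 1 year, 18 months and 2 years against the mean of 2 and 6 months, 6 arrays against 5. Fewer genes changed than in the developmental comparisons, 88 in all, 16 upward and 72 downward. With no minimum difference 532 genes passed, 298 upward and 234 downward. Some members of the collagen, corneal endothelial and retina lists fell, and none of these list results held with an estimated correlation. Col11a1 fell by 1.59 log2 units (SE 0.20, adjusted p = 8.0e-05), from 146 ± 61.9 at 2 months (n = 3) and 21.1 ± 9.61 at 6 months to 9.59 ± 3.66 at 2 years (SD, n = 2 each). Most of this fall lay between 2 and 6 months, within the younger side. The mean at 2 years lay below the 16 added before log2, so the size of the difference depends on that offset. Col6a1 fell by 1.65 and Serpinh1, the collagen chaperone, by 1.13. Ldhb, a lactate dehydrogenase gene, and Mdk gave -1.34 and -1.14, and the call of Mdk was lost without 2 months replicate 3 and without 2 years replicate 1. Agmo, an ether lipid enzyme, rose by 1.44 (SE 0.11, adjusted p = 3.5e-08), and Fetub, the fetuin B gene, Ifi203, an interferon-inducible gene, and Cyp1b1, a cytochrome P450 gene, rose by 1.53, 1.90 and 1.83. Agmo had mean intensities of 97.2 at 2 months, 225 at 1 year, 973 at 18 months and 139 at 2 years, and with 2 years alone as the older group the calls of Agmo and Ifi203 were lost.

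Of the fibrillar and associated collagens 2 of 14 fell (3 when adjusted over the list alone), and the list lay at a median of -0.52 (adjusted p = 3.2e-05 by camera, and adjusted p = 0.348 with an estimated correlation). The list's call at the preset correlation was lost when 18 months and 2 years were set against 6 months. Corneal endothelial genes fell in 3 of 9 cases (4 when adjusted over the list alone), namely Slc4a4 at -1.49, Aqp1, a water channel, at -1.31 and Cdh2 at -1.18 (adjusted p = 4.3e-06 by camera, and adjusted p = 0.0506 with an estimated correlation). With 1 array left out at a time, the call of Slc4a4 was lost without 6 months replicate 2. The call of Aqp1 held only without 2 months replicate 1 or 3, 6 months replicate 1, 1 year replicate 1 or 2 years replicate 2, and that of Cdh2 only without 1 year replicate 2 or 2 years replicate 2. The keratocyte gene Chst5, a sulfotransferase, fell by 1.11, while Kera and Lum gave -0.35 and -0.30 (adjusted p = 0.729 and 0.775). None of 9 peripheral nerve genes was called by limma (2 when adjusted over the list alone, and 5 at an unadjusted p under 0.05), and the list lay at -0.63, with adjusted p = 5.0e-04 by camera, and adjusted p = 0.0144 with an estimated correlation. None of 17 corneal epithelial products was called by limma (0 when adjusted over the list alone, and 0 at an unadjusted p under 0.05), with Aldh3a1 at 0.04 (adjusted p = 0.957 by camera, and adjusted p = 0.979 with an estimated correlation). Circadian clock genes lay at a median of 0.25 with none of 15 called (0 when adjusted over the list alone, and 7 at an unadjusted p under 0.05; adjusted p = 5.0e-04 by camera, and adjusted p = 0.197 with an estimated correlation).

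Retina genes fell in 3 of 11 cases (7 when adjusted over the list alone), with Gnat1 at -2.18 (adjusted p = 1.8e-08 by camera, and adjusted p = 0.197 with an estimated correlation), and the retina list was highest on 6 months replicate 1, one of the 5 younger arrays. Without that array, which left 6 months with 1 array, the call of Gnat1 was lost, as it was without 1 year replicate 2. At 2 years against 2 months Gnat1 gave 0.28. Of the lens genes none of 17 was called (0 when adjusted over the list alone, and 4 at an unadjusted p under 0.05), and the list lay at -1.19 (adjusted p = 6.5e-04 by camera, and adjusted p = 0.837 with an estimated correlation), with 2 of the 5 younger arrays and none of the 6 older ones rich in lens genes. Without those 2 arrays 6 months was again left with 1 array, and no count of called genes is given for that fit. The arrays of 2 months, 6 months and 2 years had Xist intensities of 5148 to 6373, those of 1 year and 18 months 34.4 to 63.4, and the Y-linked genes Uty, Kdm5d and Eif2s3y were among the 16 rising genes. With 2 years alone against 2 and 6 months, 138 genes were called, 42 upward and 96 downward. The count was 53 without 2 years replicate 1, 57 without 1 year replicate 2, 40 for 18 months and 2 years against 6 months, 207 for the same ages against 2 and 6 months, 367 for 2 years against 2 months, 353 for a trend on log2 age, and 0 with limma's test against a minimum difference of 1 log2 unit, where 2473 genes had an unadjusted p under 0.05 for any difference.

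The layers were represented by 1 array each, from different ages and different ways of isolation, so differences between them have no replicate check and no test. Krt12 had an intensity of 15150 in the P28 epithelium and 2185 in the P7 stroma. Lypd2, Tmprss11a, Krt6b and Slurp1 lay furthest toward the epithelium, with 11270, 6052, 9565 and 4365 in epithelium against 659.5, 428, 696 and 313 in stroma. Lens crystallins lay furthest toward the stroma, with Crygd at 9213 in stroma and 157 in epithelium, and so did Tnnc2, a muscle troponin gene, at 3988 against 132 and the hair keratin-associated gene Krtap16-3 at 4811 against 149.7. Crygd, Tnnc2 and Krtap16-3 had means of 90.2, 243 and 246 on the whole-cornea arrays of P7, far below the stroma array. Kera had 3433 in stroma and 158 in epithelium, and Col1a1 5261 and 457. Of 10726 genes above the array median on either array, 179 differed at least 4-fold, 63 toward the epithelium and 116 toward the stroma. The 116 include these lens, muscle and hair genes, so not all can be read as genes of the stroma.

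By group, the corneal epithelial products had a median difference of 1.59 log2 units toward the epithelium, above every one of 10000 random lists matched on expression, and 14 of 17 were higher in epithelium. The epithelial transcription factors lay at 0.78 and the circadian clock genes at 0.45, both above 99.9% of random lists. The cornified and conjunctival keratinocyte genes went the other way, at -0.42, below 99.9% of random lists, with 6 of 20 higher in epithelium. The collagens lay at -1.63, with 0 of 14 higher in epithelium, the small leucine-rich proteoglycans at -0.83, and the lens and muscle lists at -4.49 and -1.80. Among the 1335 genes that rose from E14.5 to 2 months, 83.4% were higher in the epithelium array than in the stroma array (95% interval 81.3 to 85.3, exact binomial, for counting error only), against 18.5% of the 782 that fell and 49.5% of all genes tested. The layer arrays differ in age as well, and 90.8% of these rising genes were higher at P28 than at P7, against 58.5% of all genes. With each layer set against the whole cornea of its own age, which subtracts that change, the shares were 30.0% and 60.2%. Of the 762 genes that rose before birth 48.2% were higher in the epithelium array.

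**Figure D4:**
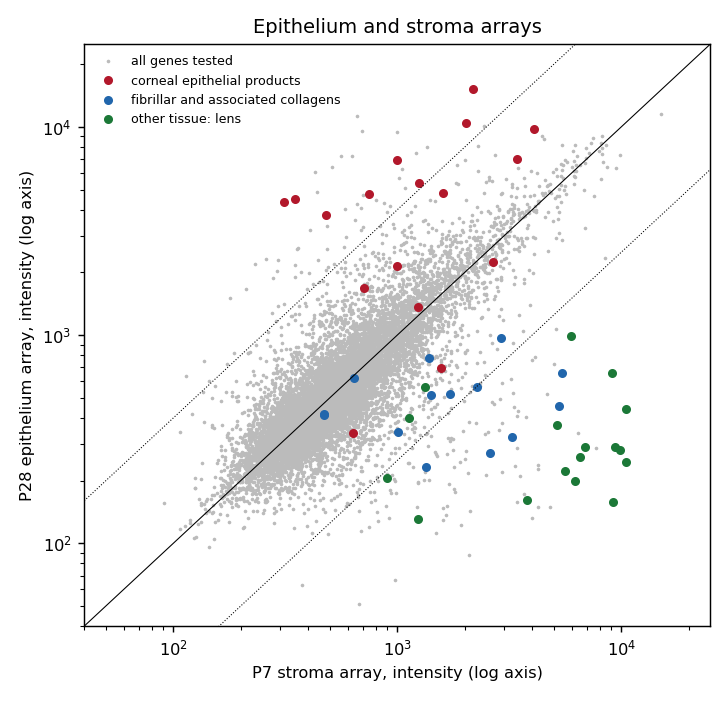
Intensity of each gene tested in the P28 epithelium (vertical, log axis) and the P7 stroma (horizontal, log axis), 1 array each, with the dotted lines at a 4-fold difference. The corneal epithelial products (red) lie mostly above the diagonal, and the collagens (blue) and lens genes (green) below it.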

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

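All tests of explanations here were chosen after the results were seen. A group of 8 probe sets without a gene, which no comparison uses, read between 1501 and 7050 on the 18 arrays of E14.5 to P14 and 12.8 or less on the 14 arrays of P28 to 2 years, a signal outside the genes tested that splits the ages.

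The 14 fibrillar and associated collagens had a median 3.10 log2 units higher at E15.5 than at E14.5, where 2 of 3 arrays were rich in lens genes and embryonic globins were high. RNA of the lens diluting the corneal RNA was looked at on the 4 lens-rich arrays of other ages. There the collagen median lay no lower than -0.27 log2 units against the other arrays of the age. Their lens list lay 2.31 to 3.85 log2 units above its 32-array median, against 4.24 and 4.20 on E14.5 replicates 2 and 3. This argues against lens RNA as the whole cause only if its share was no larger at E14.5. Replicate 1 of E14.5 was not lens-rich, at 0.47, and its collagens were not compared with those of replicates 2 and 3. RNA of embryonic blood was present, with each of the 3 embryonic globins at least 3.23 log2 units higher at E14.5 than at any other age. Its dilution of the corneal RNA would lower other stromal genes as much. The 12 periocular mesenchyme regulators rose by a median of 0.66 with an upper quartile of 1.59. This argues against dilution by blood as the whole cause only if the regulators did not themselves fall with age, which was not tested. A smaller dilution may have contributed and stays open. A change with age stays open and untested.

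From P14 to P28, 994 genes were called, at the point where the 8 probe sets without a gene split the arrays. A change of array batch as the whole cause is argued against only if the 2 layer arrays share 1 array batch. Of the genes higher at P28, 90.4% were higher in the epithelium array than in the stroma array. The share was 7.3% of the genes lower at P28 and 49.4% of all genes. Both layer arrays read 7 of the 8 probe sets at a similar level, 127 to 186, the other having no value there. That level lies between those of the 2 batches, so it places the layer arrays in neither. The layer arrays also differ in age, P28 and P7, so the split does not tell layer from age. A batch effect on part of the 994 genes stays open, because age and batch cannot be told apart between P14 and P28. So does a change with age, which was not tested apart from it.

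With ageing, 71 genes other than sex-linked ones fell, with a median of -1.23. Sex of the animals is argued against as the whole cause: with 1 year and 18 months low in Xist and 2 years high, it would put the first 2 ages 1.84 log2 units below 2 years, and their median difference in these genes was 0.13 (quartiles -0.36 and 0.59). Retinal RNA on the younger arrays is argued against as the whole cause: within 2 and 6 months, the arrays richer in retina genes exceeded the others by a median of 2.11 in the retina list and 0.04 in the 71 genes (quartiles -0.44 and 0.40), where 1.23 would be needed. A part played by either stays open. A smaller share of stroma in the older samples may have contributed and stays open: 24 stromal list genes had a median of -0.55 with quartiles of -0.95 and -0.32, going from -1.65 for Col6a1 to 0.91 for Postn. A change with age itself stays open and untested.

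Regrouping the arrays asked how often as many genes are called without the real groups. For E17.5 against E14.5, 1 of 10 splits, the real one, gave as many as 943 genes and the highest other gave 92. For P7 against E17.5, P28 against P7 and 2 months against E14.5 it was again 1 of 10, with 647, 1365 and 2117 genes against 4, 4 and 4 for the highest other. These splits are too few for a share under 0.05. In the ageing comparison 4 of 100 drawn regroupings, the real one included, gave at least 88 genes, and the highest other gave 169, more than the real groups. That regrouping had 3 of the 6 older arrays and 2 of the 4 arrays low in Xist on its older side. Chance can be excluded at 0.05 only if single arrays can be exchanged between ages. With whole ages as units there are 10 splits, too few for a share under 0.05. Of these 3 gave at least 88 genes, the real one included: 18 months and 2 years against the 3 younger ages gave 218, and 6 months, 18 months and 2 years against 2 months and 1 year gave 270, the highest. Over the 12 ages 1 of 100 gave as many as 5279 genes and the highest other 398. Here too chance can be excluded only if single arrays can be exchanged between ages.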

How the results depend on the processing

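The alternatives that left out arrays rich in another tissue, put E15.5 in place of E14.5 or P14 in place of another age, kept to 1 array batch or set 2 years against 2 and 6 months were chosen after seeing the data; the others were planned. The counts of called genes stayed within 1.5 times the reported count with no filter, a stricter filter, an offset of 1, quantile normalization, median centring, the mean or all of a gene's probe sets, trend and robust moderation, array weights and the 1A and 1B arrays averaged. With the replicate block the counts were 941, 643, 1361, 2118 and 85, in the order of the report, and 5279 over the 12 ages. Left-out single arrays gave 691 to 1141, 507 to 664, 1193 to 1657, 2066 to 2179 and 5211 to 5389 genes, and in ageing 53 (without 2 years replicate 1) to 124 (without 2 years replicate 2), with 57 without 1 year replicate 2. Where that left an age with 1 array, it was assumed to vary like the others.

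With no minimum difference the counts were 3761, 1741, 4514, 5895 and 532 (298 higher and 234 lower, where the reported ageing genes were mostly lower), and 10381 over the 12 ages, since the threshold is looser. With limma's test against a minimum log2 difference of 1 they were 155, 84, 220 (84 higher and 136 lower, against a majority higher in the reported count), 906 and 0 (ageing, with 2473 genes at an unadjusted p under 0.05 for any difference). E17.5 against E14.5 gave 529 genes with only the compared groups in the fit, 74 with E15.5 in place of E14.5 and 572 without the lens-rich arrays. P14 in place of P28 gave 0 genes by limma (819 at an unadjusted p under 0.05). Within the first array batch 2407 genes changed and within the second 892, with fewer arrays each. The ageing count was 52 with an offset of 64, 40 for 18 months and 2 years against 6 months, 367 for 2 years against 2 months, 207 for 18 months and 2 years against 2 and 6 months, 353 for a trend on log2 age and 138 for 2 years against 2 and 6 months. For the layers, the 179 genes became 372 after quantile normalization of the 34 arrays, 855 at 2-fold and 61 at 8-fold. The share of rising genes higher in epithelium became 85.5% after median centring, and 30.0% with each layer set against whole cornea of its own age. That alternative subtracts the whole-cornea change from P7 to P28, and 90.8% of these rising genes were higher at P28 than at P7, so it lowers them by construction. Gnat1 in ageing turned from -2.18 to 0.28 at 2 years against 2 months. For the ageing values and the other layer values the cause was not tested.

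Of 210 named genes, counted once per comparison, 135 kept their direction and their side of the threshold under every alternative. Over all genes and alternatives 4686 values did so, 202 lost the call, 3 gained it (Lum in ageing under 2 alternatives, Pax6 before birth) and 1 turned. Of the list results, 54 calls were lost with an estimated correlation and 3 with 18 months and 2 years against 6 months, among them the collagens in ageing, while 3 were gained: lens in the adult comparison and small leucine-rich proteoglycans in ageing with the replicate block, and pigment cells in the adult comparison with median centring. All 33 counts of the steps under the alternatives (the replicate block, no filter, median centring) stayed within 1.5 times. The replicate numbers gave no steady pairing: deviations of like-numbered arrays correlated with r between -0.29 and 0.21 across genes, which are not independent replicates. In P28 against P7 the like-numbered array was the best match for 3 of 3 arrays, with r of 0.02, 0.21 and 0.11. In the other comparisons of 2 ages examined it was the best match for 0 of 3. On arrays, signal over background limits what can be seen: a gene near the floor can fall no further, and the floor of the layer arrays, 41.8 and 42.6, hides differences between dim genes. The size of a rise from near the floor depends on the offset added before log2.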

Other observations

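The genes and steps described here were picked after their values were seen, from the fixed lists and the rule for named genes. Among genes of cornified and conjunctival keratinocytes, 8 of 20 rose before birth (9 when adjusted over the list alone; adjusted p = 9.0e-06 by camera, and adjusted p = 0.0804 with an estimated correlation), 6 of 20 rose from E17.5 to P7 (6 when adjusted over the list alone; adjusted p = 0.0018 by camera, and adjusted p = 0.178 with an estimated correlation), and from P7 to P28 2 rose and 5 fell (2 higher and 5 lower when adjusted over the list alone; adjusted p = 0.136 by camera, and adjusted p = 0.579 with an estimated correlation). The simple and mucosal keratins Krt18, Krt19, Krt8 and Krt7 lay at -1.86, -1.80, -1.33 and -1.99 from P7 to P28, and Krtdap, a keratinocyte differentiation gene, at -4.11, while Krt6a rose by 1.75. At 2 months against E14.5, 7 rose and 1 fell (7 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0147 by camera, and adjusted p = 0.307 with an estimated correlation), and in ageing 0 of 20 were called by limma (2 at an unadjusted p under 0.05; adjusted p = 0.654 by camera, and adjusted p = 0.877 with an estimated correlation). Among keratocyte genes 5 of 11 rose before birth (5 when adjusted over the list alone; adjusted p = 5.7e-04 by camera, and adjusted p = 0.0912 with an estimated correlation) and 5 of 11 from E14.5 to 2 months (5 when adjusted over the list alone; adjusted p = 0.0424 by camera, and adjusted p = 0.307 with an estimated correlation). Angptl7 rose by 3.08 from E17.5 to P7, and Tgfbi, a corneal matrix gene, by 1.93 before birth and 1.34 from P7 to P28. In ageing 1 of 11 keratocyte genes fell (1 when adjusted over the list alone; adjusted p = 0.00672 by camera, and adjusted p = 0.197 with an estimated correlation).

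Of 13 glycolysis genes, Slc2a1 was the 1 that fell from E17.5 to P7 (1 when adjusted over the list alone; adjusted p = 4.3e-04 by camera, and adjusted p = 0.178 with an estimated correlation), and Ldhb the 1 that fell in ageing (1 when adjusted over the list alone; adjusted p = 0.159 by camera, and adjusted p = 0.848 with an estimated correlation). Antioxidant and detoxifying enzymes rose in 7 of 21 cases from E14.5 to 2 months (7 when adjusted over the list alone; adjusted p = 0.104 by camera, and adjusted p = 0.54 with an estimated correlation), with Nqo1 at 2.47 and Gsta4 at 2.24, while Cyp1b1 lay at -3.65 there and at -2.73 from P7 to P28. Among leukocyte and macrophage genes 1 of 14 rose and 1 fell from E14.5 to 2 months (1 higher and 1 lower when adjusted over the list alone; adjusted p = 0.154 by camera, and adjusted p = 0.54 with an estimated correlation), Itgam, an integrin of myeloid cells, at 3.08 and Tyrobp at -1.18. In ageing 0 of the 14 were called by limma (2 at an unadjusted p under 0.05; adjusted p = 0.471 by camera, and adjusted p = 0.877 with an estimated correlation), and 0 of 9 senescence and secretory genes (0 at an unadjusted p under 0.05; adjusted p = 0.928 by camera, and adjusted p = 0.979 with an estimated correlation). Immediate early and heat shock genes rose in 4 of 15 cases from E14.5 to 2 months (4 when adjusted over the list alone; adjusted p = 0.333 by camera, and adjusted p = 0.631 with an estimated correlation), with Hspa1a, a heat shock protein gene, at 4.05 and Junb at 2.62. Of the 2 lacrimal and meibomian gland genes tested, Scd1 rose by 2.14 from P7 to P28, and no list test was made.

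Neurod4, Otx2 and Fabp7 had mean intensities of 2895, 2252 and 5072 at P3 against 99.4, 151 and 369.9 at P7. The median of the 11 retina genes lay 0.16 to 0.92 log2 units above its 32-array median on the P3 arrays and at -0.40 to -0.16 on those of P7. From P3 to P7 the retina genes Crx and Rlbp1 gave -1.51 (adjusted p = 0.0274) and -1.19 (adjusted p = 0.0041), and the other 9 were not called. Among the adult ages, Rtp4, Sp100 and Ifit1, genes of the interferon response, were higher at 6 than at 2 months by 2.73, 2.15 and 2.11 log2 units. They are the 3 named genes with the largest rise in that step, and no list was tested there. With no filter, 0.89% of olfactory receptor genes were called in it, against 0.91% of all genes. From 1 year to 18 months Ednrb, an endothelin receptor gene, and Cldn10, a claudin gene, gave -4.17 and -3.55. Pdc and Gnat1, photoreceptor genes, were higher at 2 years than at 18 months by 4.87 and 4.11, with intensities of 36.7 and 138 at 18 months and 1449 and 2519 at 2 years. Each of 6 months, 1 year, 18 months and 2 years has 2 arrays, and those of 1 year and 18 months were low in Xist.

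Over the means of the 6 ages of the later batch, the clock gene Ciart against Arntl gave r = -0.94 by an exact permutation test with p = 0.0111, rho = -0.94 with exact p = 0.0167, and r = -0.95 without the 2 ages farthest from the median of Arntl. This was 1 of 7 such relations, chosen after seeing the data, and with adjustment over the 7 none passed: 5 had an adjusted p = 0.0739 and 2 had an adjusted p = 0.574 (exact permutation tests).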
